A study of Homo sapiens with 12 samples.

How the data were processed

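RNA was profiled in 12 xenograft tumours grown in mice from H3122, an established human lung adenocarcinoma cell line that carries the EML4-ALK fusion. Per the labels, 2 tumours were controls, 4 came from mice given the ALK inhibitor ceritinib at 75 mg/kg, 3 from 87.5 mg/kg and 3 from 100 mg/kg. Per the labels, total RNA was purified on columns, converted to biotinylated cRNA and hybridized to Illumina Expression BeadChips. The scanner software, the slides and any labelling batches were not given in the sources used here.

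The authors provided 1 average bead signal intensity per probe and array on a linear scale, in a text table and again in a value table. The deposited intensity values had no normalization and no background subtraction, with signals from 61.2 to 68257. The text table also gave, per the file headers, a detection p-value per probe and array. Both tables held the same 12 signals at the same position for all 47323 probes, but their probe identifiers matched at 1 position. Probes assigned to 1 gene had mean log2 signals that correlated at 0.467 with the identifiers of the value table and at 0.0577 with those of the text table. The median log2 signal of GAPDH was 14.7 with the former and 8.92 with the latter. The identifiers of the value table were therefore used, and the detection p-values were joined through the identical signals. The plan had foreseen a normalized value table, so its alternative became the signals on the log2 scale without normalization.

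Gene symbols came from the table of probes and genes for this array, in which 30113 probes had 1 symbol, 8 had several and 17202 had none. Of these probes, 30074 had an Entrez identifier in a RefSeq gene table, which updated 0 symbols. The files named no genome build, so genes are given by symbol, without positions. Probes without a symbol were left out of the tests by gene. Signals were background corrected with negative controls inferred from the detection p-values, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 (offset 16) in R 4.3.3 with the data.table package (1.17.8). Probes with a detection p under 0.01 on at least 2 arrays were kept, which left 20889, and the probe with the highest mean stood for each gene. This gave 12300 tested genes, of which 3228 had several probes to choose from. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

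The 4 groups were fitted together in limma with moderated standard errors, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Because the control group held 2 tumours, the spread was estimated from all 12. The treated tumours were compared with the controls through the unweighted mean of the 3 dose groups, each dose was compared with the controls, and the doses with each other. Written before the data were examined were 31 gene lists from general knowledge, the comparisons, the alternatives and the rule for named genes. Lists with at least 5 measured genes were tested against all other genes with camera of limma at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction, were run beside it. Values in the text are log2 differences with their standard error (SE) or group means with their standard deviation (SD). Where no array of 1 group detected a gene, the fold is a lower bound. For it, each undetected signal was replaced, where lower, by the lowest signal that passed detection on that array. Means given for the 10 treated tumours weight each tumour alike, while log2 differences weight each dose alike.

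Named genes were 12 study genes, the 10 highest and 10 lowest changes in treated tumours among genes past the threshold whose treated tumours all lay on 1 side of both controls, the 4 highest and 4 lowest per dose, and the 3 highest and 3 lowest per pair of doses. Where a pair of doses had 0 genes past the threshold, the 2 with the smallest p were taken. Each list added up to 4 members with the smallest p, and uncharacterised identifiers were passed over. Other members that spell out a count of 5 or fewer in a list were chosen after their values were seen.

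The fit was tested on simulated data, in which 200 of 12300 genes were changed. In treated against control tumours it recovered 73% of changes of log2 1 and 96% of changes of log2 2, and 3.43% of its calls were false. Camera called the shifted list and also 2 lists that were not shifted. Alternatives were tried for background, offset, normalization, detection filter, probe choice, spread model, array weights, samples in the fit, a block for replicate number, the set test, an added fold threshold and leaving out each tumour. Probe names from the text table were an alternative chosen after seeing the data. For arrays, precision is limited by their number.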

Results

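Gene expression was measured in 12 H3122 tumours, 2 controls and 10 treated with ceritinib. Per the study's description, the treated tumours first shrank and then acquired resistance. The question named in the title concerns epithelial-mesenchymal transition, the loss of epithelial in favour of mesenchymal traits, in resistance to ALK inhibitors. Each array detected between 17993 of 47323 probes (38%, replicate 4 at 75 mg/kg) and 19478 (41.2%, control replicate 2). Median signals per array ranged from 134.5 to 147. The limma p-values of single genes measure the spread between tumours, and the labels do not say whether each tumour came from its own mouse.

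Controls and treated tumours separated on the first principal component, which held 41.9% of the variance. The controls lay at -54.3 and -52.8 and the treated tumours between -10.1 (replicate 2 at 87.5 mg/kg) and 29.9 (replicate 2 at 100 mg/kg). On the second component, with 17.6%, replicate 2 at 87.5 mg/kg stood apart at 39.7, against -25.9 to 18.9 for the others. Array correlations ranged from 0.9356 to 0.9898.

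**Figure D1:**
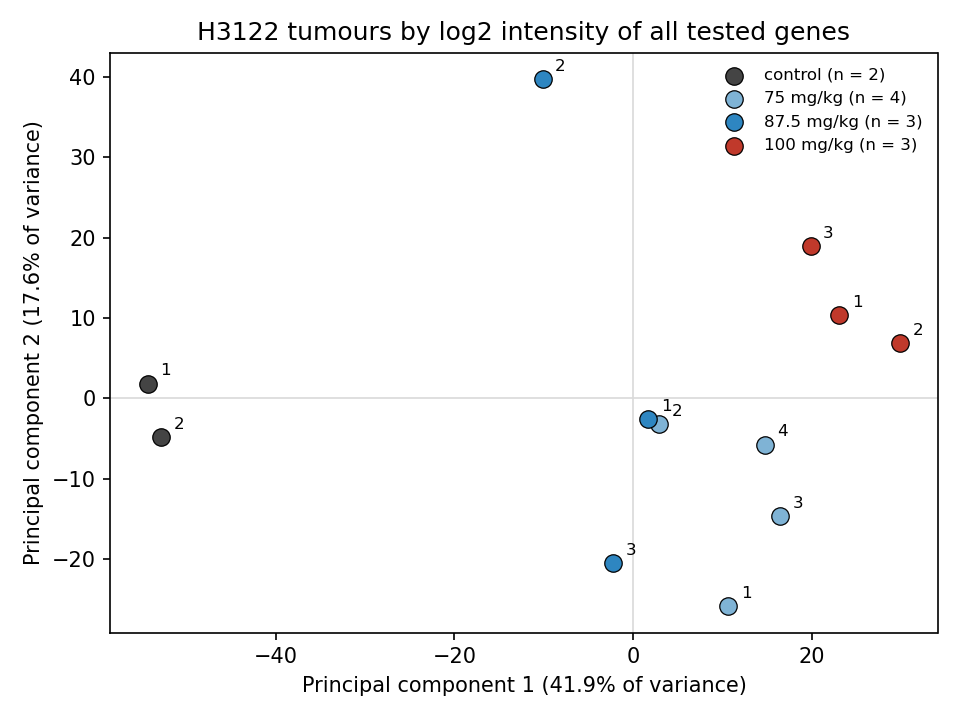
Each point is 1 tumour, coloured by group and numbered by replicate, on the first (41.9% of variance) and second (17.6%) principal component of log2 signal over all tested genes. The 2 controls lie at -54.3 and -52.8 on the first component, apart from all 10 treated tumours, and replicate 2 at 87.5 mg/kg lies highest on the second at 39.7.

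Tumours under ceritinib were compared with the controls to ask how they differed. The labels name no treated tumour from before resistance and no resistant tumour off the drug. Effects of ceritinib and traits of acquired resistance therefore cannot be told apart here. Surfactant protein genes of alveolar cells rose, with SFTPB from 8.07 ± 0.34 (log2 signal, SD, n = 2) to 12.65 ± 0.52 (n = 10), a 23.3-fold difference, and SFTPD 19.9-fold (log2 4.31, SE 0.26). The airway secretory gene SCGB3A1 rose 32.6-fold (log2 5.03, SE 0.70, adjusted p = 0.000651) and TESC, which encodes a calcium-binding protein, 29.1-fold (SE 0.43 on the log2 scale). The cell adhesion gene CDH6 was 14.5-fold lower (log2 -3.86, SE 0.29, adjusted p = 1.58e-05), and FHL2, a LIM domain protein gene, 9.3-fold (log2 -3.22, SE 0.42). All 10 treated tumours lay beyond both controls for each of these 6 genes, which the rule that picked them required.

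The other genes with the highest changes were not detected in either control. HHATL was at least 16.6-fold higher (adjusted p = 2.13e-05), KIF5C, a neuronal kinesin gene, at least 16-fold, MAL at least 11.9-fold, NEB at least 11-fold, DAAM2 at least 9.73-fold and GNLY at least 7.26-fold. Among the lowest, SHISA3 (at least 6.45-fold lower), the neural transcription factor gene ZIC2 (at least 4.81-fold, adjusted p = 4.52e-06) and thrombomodulin THBD (at least 4.22-fold) were detected in both controls and in 0 of 10 treated tumours. FHOD3 (log2 -3.64, detected in 1 of 10), PADI3 (log2 -2.96, in 2 of 10), ALDH1A2 (log2 -2.92, in 7 of 10) and MCTP1 (log2 -3.07) fell as well. IGFBP3 fell 9.97-fold (SE 0.80 on the log2 scale, adjusted p = 0.0147), and lost its call without control replicate 1 (adjusted p = 0.0914) or 2 (0.129).

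Of the genes the study concerns, the epithelial cadherin gene CDH1 fell by 0.59 (SE 0.12, adjusted p = 0.00689), from 13.89 to 13.3 ± 0.15 (SD, n = 10). The mesenchymal markers VIM and CDH2 were lower too, VIM at log2 -0.94 (SE 0.24, adjusted p = 0.0206) and CDH2, the neural cadherin gene, at log2 -2.36 (SE 0.30, adjusted p = 0.000412). MET fell by 0.78 (SE 0.14) and the deacetylase gene HDAC1 by 0.54 (SE 0.12). ALK had a log2 difference of 0.67 (SE 0.37, adjusted p = 0.239), EML4 0.00 (SE 0.12) and HDAC2 0.00 (SE 0.13), and none of these passed. AXL had -0.94 (adjusted p = 0.0596) and was detected in 1 of 10 treated and 1 of 2 control tumours. It passed as lower with unnormalized signals (log2 -0.53, adjusted p = 0.0161), median scaling (adjusted p = 0.0401) or array weights (adjusted p = 0.0398). CDC20B, whose locus hosts miR-449, was at least 1.18-fold higher without passing (adjusted p = 0.321). It was detected in 4 treated tumours alone, at 7.29 and 7.18 for 75 mg/kg and 7.62 and 8.46 for 100 mg/kg, and its mean at 87.5 mg/kg was 5.34 against 5.38 in controls. ZEB1 and SNAI1, repressors of CDH1, had 1 probe each, detected on 0 arrays. The calls of CDH1 and VIM were lost without control replicate 1 (adjusted p = 0.0791 and 0.094) or 2 (0.0596 and 0.18), and those of MET (0.0548) and HDAC1 (0.222) without replicate 1. Without replicate 3 at 87.5 mg/kg, ALK passed at log2 0.85 (adjusted p = 0.027).

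**Figure D2:**
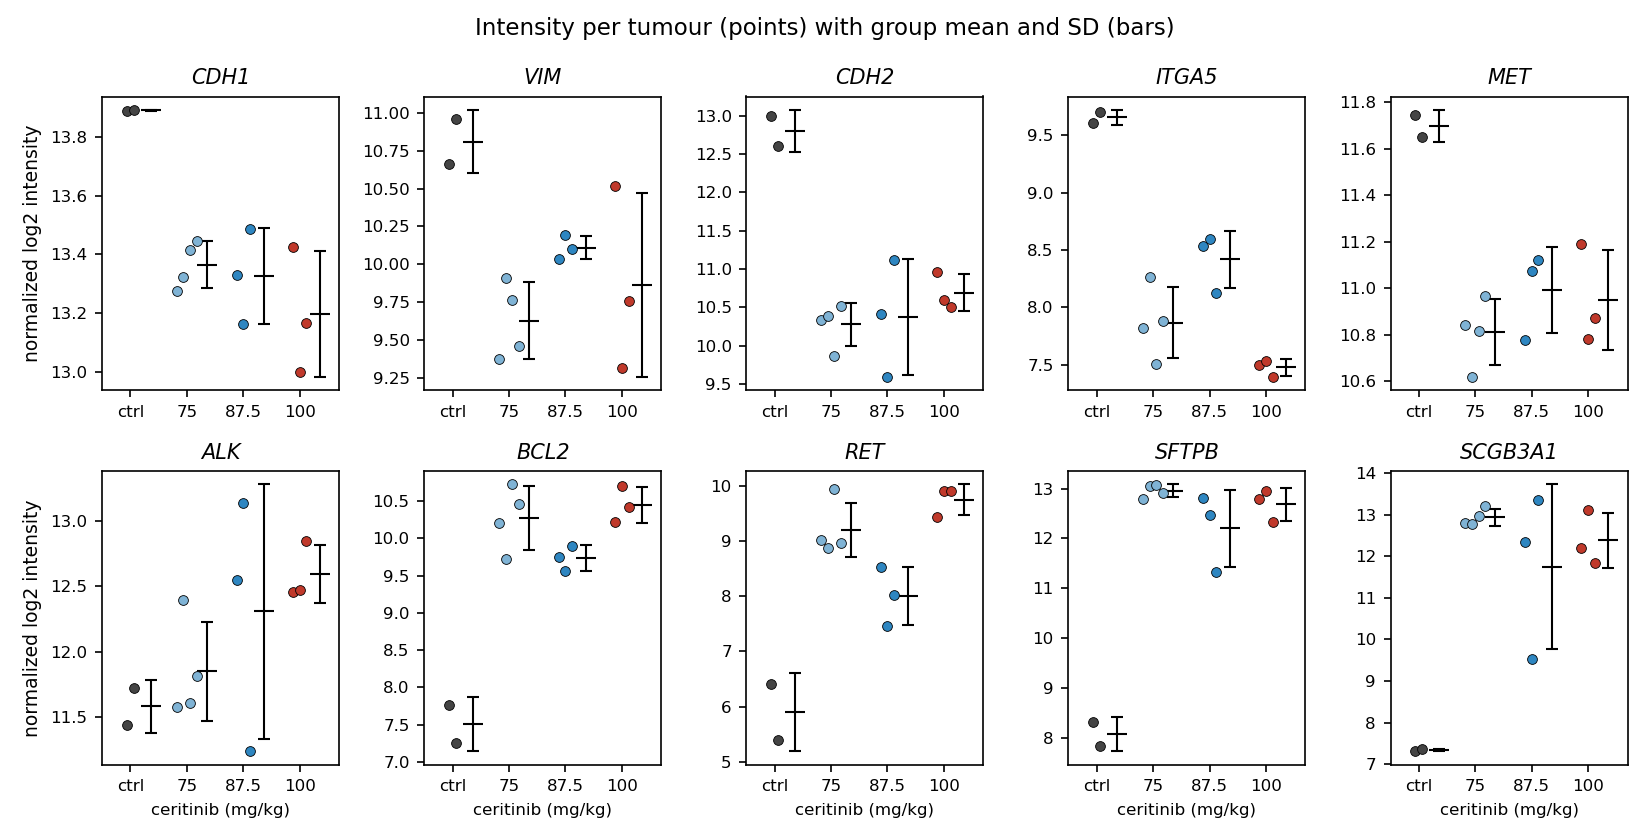
Log2 normalized signal of 10 genes in each tumour (points) by ceritinib dose, with the group mean and SD as bars (n = 2, 4, 3 and 3). CDH1, VIM, CDH2 and MET lie lower and SFTPB, SCGB3A1, RET and BCL2 higher in treated than in control tumours, while ALK did not pass the test (adjusted p = 0.239).

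In all, 2318 of 12300 genes changed in treated tumours (limma, n = 10 against 2), 1215 higher and 1103 lower, and 823 of them more than 2-fold. Of all 12300 genes, changed or not, 1414 lay above both controls in all 10 treated tumours and 1359 below, together 22.5%, where chance gives 3.03%. The count fell to 719 without control replicate 1 and to 1205 without control replicate 2. With arrays scaled to 1 median in place of quantile normalization, 836 of 2611 changed genes were higher, and the median change of all genes was -0.11 in place of 0.02.

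Among the gene lists, 13 of 31 differed from the other genes by camera at the preset correlation, 1 upward and 12 downward. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.0904, although 8 had an unadjusted p under 0.05. Fry called 14 lists, and where it differed from camera this is given beside the list. Calls of list members outside the rule for named genes, such as SIRT4, KAT5 and FGFR3, were not followed under the alternatives. A missing p-value beside such a member therefore does not show that its call held. Of 109 named gene results past the threshold here, 46 lost it without control replicate 1 and 31 without replicate 2, with the p-values beside the genes described.

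Integrins, laminins and other basement membrane genes were lower. Of 20 measured, 11 fell and 0 rose (15 and 0 adjusted over the list alone), among them ITGA2 (log2 -1.82, SE 0.21), ITGB4 (log2 -1.41), LAMB1 (log2 -1.60) and ITGA5 (log2 -1.74, SE 0.17). The list's median was -0.96 (camera adjusted p = 1.09e-07, adjusted p = 0.0904 with an estimated correlation). Mesenchymal markers were lower, with 14 of 29 fallen and 1 risen (17 and 2 adjusted over the list alone). COL5A1 (log2 -2.79, detected in 4 of 10), CDH11 (log2 -1.81, SE 0.23) and SNAI2 (at least 1.59-fold lower) fell and CALD1 rose (log2 0.96). The bound for SNAI2 was 2.29-fold without control replicate 1 and 1.1-fold without control replicate 2. The median was -0.94, or -0.86 with 3 dim genes at their bounds (adjusted p = 1.21e-05, adjusted p = 0.126 with an estimated correlation). Epithelial markers were lower as well, 12 of 34 fallen and 0 risen (13 and 0 adjusted over the list alone), with the keratin gene KRT7 at log2 -1.01 (SE 0.17) and CDS1 at -0.82 (SE 0.13). KRT19 was at log2 -0.64, its call lost without control replicate 1 (adjusted p = 0.205). The epithelial median was -0.35 (adjusted p = 0.000132, adjusted p = 0.093 with an estimated correlation).

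Of 11 transcription factors of the transition, SNAI2 fell and SOX9 rose (log2 1.17, adjusted p = 0.104 without control replicate 1 and 0.19 without 2). Adjusted over the list alone, 2 fell and 1 rose, and camera did not call the list (adjusted p = 0.29, adjusted p = 0.409 with an estimated correlation), while fry called it downward (adjusted p = 0.00226). TGF-beta targets had 5 fallen and 1 risen of 21 (9 and 3 adjusted over the list alone). TGFBR2 (log2 -1.03, SE 0.15), SMAD6 (log2 -1.23), TGIF1 (log2 -0.38), PMEPA1 (log2 -0.99, adjusted p = 0.0673 without control replicate 1) and BHLHE40 (log2 -0.99, 0.0688 without it) fell. ID3 was at least 2.89-fold higher (adjusted p = 0.0565 without control replicate 2). That list's call (median -0.25, adjusted p = 0.046, adjusted p = 0.148 with an estimated correlation) was lost in 10 settings, among them without control replicate 2 (0.116). Targets of YAP and TAZ were lower, 9 of 20 fallen and 1, AMOTL2 (log2 0.55), risen (11 and 2 adjusted over the list alone). NT5E (log2 -1.97, SE 0.28), F3 (log2 -2.03, SE 0.31) and CRIM1 (log2 -1.98, detected in 1 of 10) fell (median -0.71, adjusted p = 0.000824, adjusted p = 0.133 with an estimated correlation).

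Receptor kinases, their ligands and signalling proteins such as FYN and IRS1 moved both ways, 5 up and 4 down of 25 (6 and 7 adjusted over the list alone). The receptor genes RET (log2 3.08, SE 0.33, detected in 1 of 2 controls) and KIT (log2 2.68, SE 0.27) rose with HBEGF (log2 1.78), FYN (log2 0.96) and EGF (log2 1.60, adjusted p = 0.058 without control replicate 1). FGFR3 (log2 -2.27), IRS1 (log2 -1.64, SE 0.15), EGFR (log2 -1.07) and MET fell, and neither camera nor fry called the list (median -0.21 but mean 0.06, adjusted p = 0.693, adjusted p = 0.737 with an estimated correlation). Feedback genes of the ERK pathway, which lies downstream of ALK, had 6 fallen and 1, SPRY1 (log2 0.47), risen of 21 (9 and 2 adjusted over the list alone). The phosphatase gene DUSP5 (log2 -2.12, SE 0.29), EPHA2 (log2 -1.69, adjusted p = 0.0536 without control replicate 2) and SPRY2 (log2 -0.62, 0.0789 without control replicate 1) fell. The median was -0.53 (adjusted p = 0.0144, adjusted p = 0.394 with an estimated correlation), and the call was lost without control replicate 2 (0.0562) and with unnormalized signals (0.0544).

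Reported targets of miR-34 and miR-449, a list from general knowledge, had 10 fallen and 2 risen of 32 (13 and 2 adjusted over the list alone), with a median of -0.35 (adjusted p = 0.00544, adjusted p = 0.13 with an estimated correlation). BCL2, an inhibitor of cell death, rose 6.26-fold (log2 2.65, SE 0.23, adjusted p = 3.37e-05) and E2F3 rose (log2 0.44). CCNB1 (log2 -1.21, adjusted p = 0.075 without control replicate 1) and JAG1 (log2 -1.04, 0.0916 without replicate 1 and 0.0505 without 2) fell, with MET and HDAC1. Genes of deacetylase and acetyltransferase families had 5 risen and 2 fallen of 25 (6 and 2 adjusted over the list alone) and a median of 0.00 (adjusted p = 0.85, adjusted p = 0.927 with an estimated correlation). HDAC5 (log2 0.82, adjusted p = 0.191 without control replicate 1), SIRT4 (log2 0.55), KAT5 (log2 0.51), KAT8 (log2 0.44) and KAT2A (log2 0.38, 0.149 without replicate 1 and 0.193 without 2) rose. HDAC1 and EP300 (log2 -0.67, 0.107 and 0.077) fell.

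Mitotic and S-phase genes were lower, 13 of 42 fallen and 1, MCM7 (log2 0.48), risen (19 and 1 adjusted over the list alone). The cyclin gene CCNA2 fell by 1.00 (SE 0.16), PLK1 by 0.96 (adjusted p = 0.0705 without control replicate 1) and BUB1B by 0.67 (0.0856 without it). The median was -0.41 (adjusted p = 4.4e-05, adjusted p = 0.409 with an estimated correlation). Genes induced by low oxygen had 9 of 32 fallen and 1 risen (11 and 1 adjusted over the list alone). The glucose transporter gene SLC2A1 (log2 -1.85, SE 0.31) and STC2 (log2 -1.76, adjusted p = 0.131 without control replicate 1 and 0.147 without 2) fell and BNIP3 rose (log2 0.71, 0.131 and 0.147). Their median was -0.46 (adjusted p = 0.00119, adjusted p = 0.549 with an estimated correlation), and fry did not call it (0.118). Immediate early and heat shock genes, which respond to tissue handling, had 4 fallen and 1 risen of 24, and the same counts adjusted over the list alone. Of those fallen, HSPA1B lay at 12.05 to 12.53 at 100 mg/kg but at 13.26 to 13.40 at the lower doses (controls 13.85 and 13.40). KLF6 (log2 -0.83, adjusted p = 0.104 without control replicate 2), KLF4, HSPA6 (log2 -1.43) and HSPA1B (log2 -0.62, 0.231 without control replicate 1) fell and HSPB1 rose (log2 0.45, 0.0935 without replicate 1 and 0.195 without 2). The call of this list (median -0.32, adjusted p = 0.0191, adjusted p = 0.409 with an estimated correlation) was lost without control replicate 1 (0.0688) and with unnormalized signals (0.0555), and fry did not call it (0.0692).

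Genes of alveolar and airway secretory cells were the list called upward, with 8 risen and 4 fallen of 21 (12 and 5 adjusted over the list alone). Besides SFTPB, SFTPD and SCGB3A1, ABCA3, a lipid transporter gene of alveolar type II cells, rose (log2 1.05, SE 0.16), as did the lung transcription factor gene NKX2-1 (log2 0.70). The mucin genes MUC1 (log2 -1.64) and MUC5B (log2 -1.08), FOXA2 (log2 -1.05) and SLC34A2 (log2 -0.94) fell. The median was 0.59 (adjusted p = 0.0157, adjusted p = 0.159 with an estimated correlation). Squamous genes were lower, 7 of 19 fallen and 1 risen (10 and 2 adjusted over the list alone). KRT14 was at least 2.81-fold lower (at least 1.73-fold without control replicate 2), S100A8 at least 1.32-fold and SPRR3 had log2 -2.57 (detected in 1 of 10), while CALML3 rose (log2 3.53, SE 0.31). The median of -1.26 became -0.70 with dim genes at their bounds. That list's call (adjusted p = 0.00174, adjusted p = 0.0904 with an estimated correlation) was lost without control replicate 2 (0.0593) and among genes detected on at least 6 arrays (median -0.70, 0.212).

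With the settings used throughout, camera called no other tumour cell list, and fry called drug transport and detoxification genes alone of these, downward (adjusted p = 0.013). Apoptosis regulators had BCL2 risen and the pro-apoptotic genes BID (log2 -1.46, SE 0.15), BIK (log2 -1.51, SE 0.27) and PMAIP1 (log2 -1.39) fallen of 19, with the same counts adjusted over the list alone (adjusted p = 0.227, adjusted p = 0.409 with an estimated correlation, 0.0442 at the preset correlation without control replicate 1). Targets of p53 had 4 risen, SESN1 (log2 0.85), RRM2B (log2 1.07, adjusted p = 0.203 without control replicate 1), TP53INP1 (log2 0.70, 0.0908 without replicate 1 and 0.111 without 2) and TP53I3 (log2 0.50), and 1 fallen, PLK2 (log2 -1.83), of 20 (4 and 1 adjusted over the list alone; adjusted p = 0.3, adjusted p = 0.737 with an estimated correlation). Of 9 neuroendocrine genes SCG5 rose (log2 2.82, SE 0.22; 1 adjusted over the list alone; median 0.62, or 0.038 at the bounds; adjusted p = 0.227, adjusted p = 0.615 with an estimated correlation, 0.0459 at the preset correlation with unnormalized signals). Stem-like markers had 2 fallen of 16, ALDH1A1 (log2 -2.10, 0.238 without control replicate 1) and KLF4 (log2 -1.55, 0.126 without replicate 1 and 0.134 without 2), and 2 adjusted over the list alone (adjusted p = 0.29, adjusted p = 0.409 with an estimated correlation). Drug transport and detoxification genes had 4 fallen and 1 risen of 20 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0944, adjusted p = 0.336 with an estimated correlation). Camera called them without a detection filter (0.0285) and without replicate 2 at 87.5 mg/kg (0.0498). TXNRD1 (log2 -1.22, 0.0562 without control replicate 1), NQO1 (log2 -0.53, 0.203 without it), HMOX1 (log2 -0.75) and ABCC3 (log2 -0.86, 0.0842 without replicate 1 and 0.245 without 2) fell and GSTM3 rose (log2 0.69, 0.325 without replicate 1).

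Interferon-induced genes moved both ways, 4 up and 4 down of 37, with the same counts adjusted over the list alone. HERC5 (log2 0.95, SE 0.15), OAS3 (log2 0.77, SE 0.14), GBP1 (log2 0.94) and PARP12 (log2 0.49) rose, and IFITM1 (log2 -2.15, adjusted p = 0.065 without control replicate 1), BST2 (log2 -1.43, 0.122 without replicate 1 and 0.0718 without 2), IFITM2 (log2 -1.25) and PARP9 (log2 -0.71) fell. Their median was 0.01 and their mean -0.09 (adjusted p = 0.84, adjusted p = 0.927 with an estimated correlation). Antigen presentation had TAP2 (log2 -0.59, 0.125 and 0.056 without each control) and HLA-E (log2 -0.51, 0.0697 and 0.256) fallen of 15, and 2 adjusted over the list alone (adjusted p = 0.315, adjusted p = 0.737 with an estimated correlation). Of 21 NF-kappaB and inflammatory genes TNFAIP2 rose (log2 0.98, 0.0973 without control replicate 1), and 1 adjusted over the list alone (adjusted p = 0.693, adjusted p = 0.927 with an estimated correlation). Cholesterol synthesis had MVD (log2 0.75, 0.0753 without control replicate 2) and PMVK (log2 0.34, 0.378 and 0.0549 without each control) risen of 20, and 1 adjusted over the list alone (adjusted p = 0.307, adjusted p = 0.75 with an estimated correlation). The unfolded protein list had PCK2 (log2 0.61, 0.217 and 0.124) risen of 25, and 0 adjusted over the list alone (adjusted p = 0.693, adjusted p = 0.927 with an estimated correlation). Of 40 ribosomal protein genes RPL28 (log2 0.53, 0.199 and 0.093), RPL13 (log2 0.44, 0.262 and 0.0658) and RPL14 (log2 0.50, 0.227 and 0.218) rose, and 0 adjusted over the list alone (adjusted p = 0.29, adjusted p = 0.615 with an estimated correlation, 0.0463 at the preset correlation with median scaling). Of 6 metallothioneins 0 changed, also adjusted over the list alone, with MT1X at log2 -0.90 (adjusted p = 0.3 for the list, adjusted p = 0.737 with an estimated correlation).

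Xenografts hold mouse stroma, whose RNA can bind human probes to an unknown extent, so 4 lists of host cell markers were measured. Fibroblast markers had 6 of 11 fallen and 0 risen (6 and 1 adjusted over the list alone), with COL6A1 at log2 -1.41 (detected in 2 of 10, adjusted p = 0.0612 without control replicate 2) and LUM at -2.17 (0.152 without replicate 1 and 0.104 without 2), and 9 of the 11 also stand in the mesenchymal list. Their call (median -0.75, adjusted p = 0.0332, adjusted p = 0.286 with an estimated correlation) was lost in 8 settings, among them without control replicate 2 (0.069), and among genes detected on at least 6 arrays their median was 0.0988. Of 5 endothelial markers VWF rose (log2 2.02, SE 0.39, 0.072 without control replicate 1) and SOX18 fell (log2 -1.20, 0.065 without it; 4 and 1 adjusted over the list alone; adjusted p = 0.29, adjusted p = 0.409 with an estimated correlation), and fry called the list upward (adjusted p = 0.00163). Of 10 macrophage markers CD163 (at least 1.6-fold) and CTSS (log2 0.81) rose and LAPTM5 (at least 3.16-fold) and S100A8 fell (2 and 3 adjusted over the list alone). That list's median was 0.30 and its mean -0.29 (adjusted p = 0.958, adjusted p = 0.964 with an estimated correlation). Of 8 blood, fat and muscle markers LPL was at least 2.32-fold higher (0.127 and 0.0833 without each control; 1 adjusted over the list alone; adjusted p = 0.227, adjusted p = 0.44 with an estimated correlation).

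**Figure D3:**
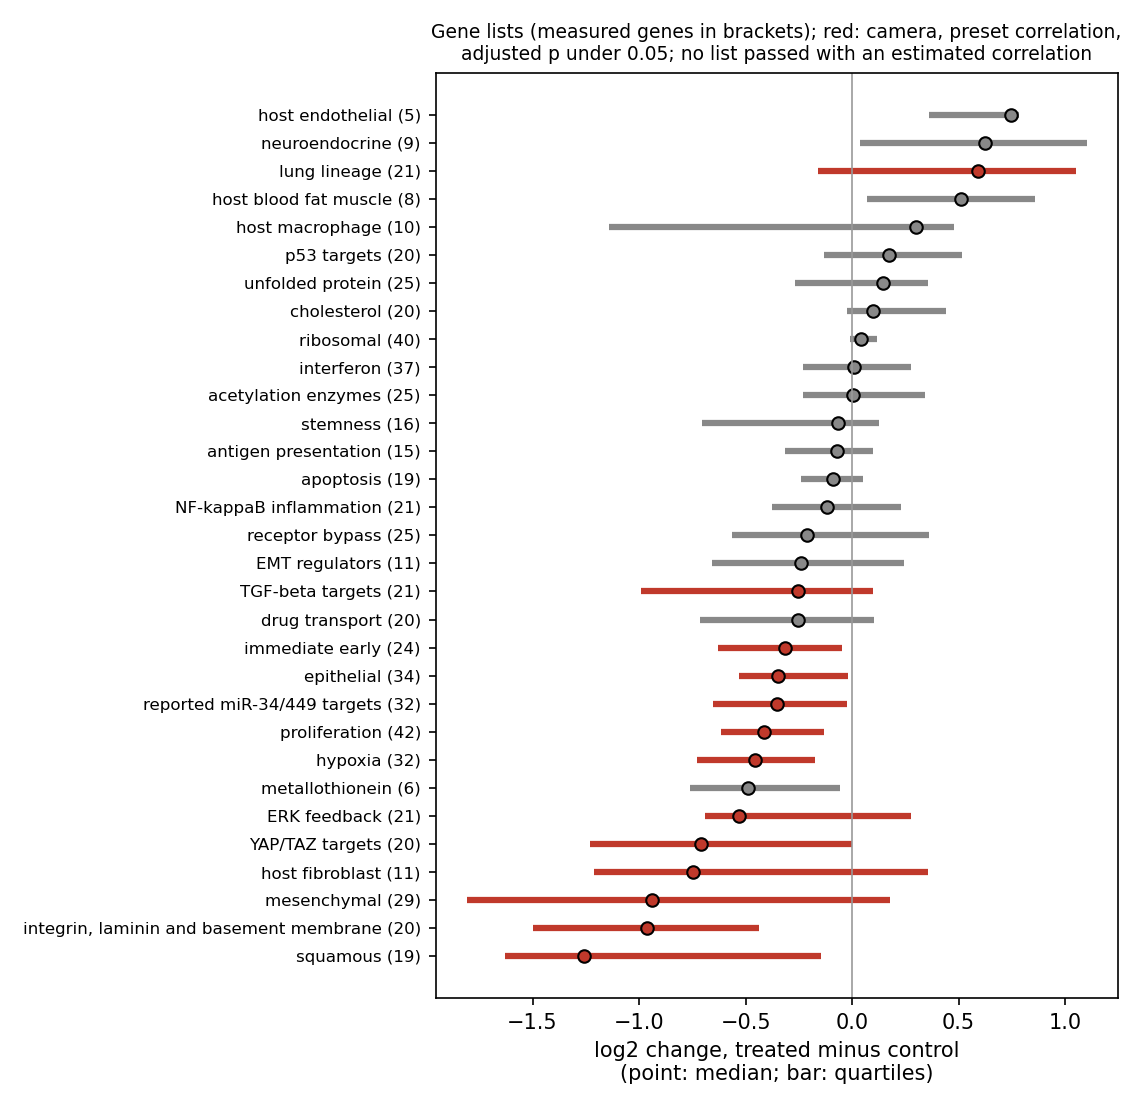
Median log2 difference between treated and control tumours in each of the 31 gene lists (points) with quartiles (lines), red where camera at the preset correlation gave an adjusted p under 0.05. The squamous list lies lowest (-1.26), followed by the adhesion list (-0.96) and mesenchymal list (-0.94). The lung lineage list (0.59) lies high, below the endothelial (0.746) and neuroendocrine (0.622) lists, which camera did not call. These positions include dim genes at their fitted values. With such genes at their bounds, the squamous median was -0.70 and the mesenchymal -0.859, while the adhesion median stayed at -0.964. The endothelial median was then 0.36 and the neuroendocrine 0.038, below the lung lineage median of 0.589. With an estimated correlation 0 lists passed.

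At 75 mg/kg (n = 4 against 2) SCGB3A1 rose 48.9-fold (log2 5.61, SE 0.78, adjusted p = 0.000866), SFTPB by log2 4.88 (SE 0.34) and TESC by log2 4.52, and HHATL was at least 18.3-fold higher. CDH6 was lower by log2 -3.74 (SE 0.33, adjusted p = 5.32e-05), FHL2 by -3.49 (SE 0.46) and FHOD3 at least 7.04-fold. IGFBP3 had log2 -3.65 (adjusted p = 0.0189), lost without control replicate 1 (0.0944) or 2 (0.12). In all 1784 genes changed, 907 higher and 877 lower, and 12 lists were called (0 with an estimated correlation, smallest adjusted p = 0.0885). The count was 556 without control replicate 1 and 1107 without 2, and with median scaling 595 of 2447 genes were higher.

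At 87.5 mg/kg (n = 3 against 2) TESC rose by log2 4.57 (SE 0.51, adjusted p = 0.00051) and SFTPB by 4.13 (SE 0.36), and HHATL was at least 12-fold higher (18.6-fold without replicate 3). SCGB3A1 was higher by log2 4.42 (adjusted p = 0.00985), a call lost without control replicate 1 (0.0905) or 2 (0.0543). CDH6 (log2 -3.30, SE 0.35), the intestinal mucin gene MUC2 (log2 -2.90, SE 0.39), FHOD3 (log2 -3.12, detected in 1 of 3) and SHISA3 (at least 6.53-fold) were lower. In all 760 genes changed, 400 higher and 360 lower, and 9 lists were called (0 with an estimated correlation, smallest adjusted p = 0.171). The count was 179 without control replicate 1, 451 without control replicate 2 and 470 without replicate 1 at 87.5 mg/kg, and with median scaling 288 of 1057 genes were higher.

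At 100 mg/kg (n = 3 against 2) TESC rose by log2 5.49 (SE 0.51, adjusted p = 5.04e-05), and KIF5C was at least 37.2-fold, SMOC2, a secreted matrix protein gene, at least 27.3-fold and HHATL at least 20.9-fold higher. The size for SMOC2 came from replicate 3, at 13.75 against 9.23 and 9.56 in replicates 1 and 2, and the bound was 9.99-fold without it. CDH6 (log2 -4.53, detected in 1 of 3) and FHL2 (log2 -4.11, SE 0.49) fell. IGFBP3 had log2 -4.14 (adjusted p = 0.00955, 0.0731 without control replicate 2). ANGPTL4 had log2 -4.33 (SE 1.29, adjusted p = 0.0339), lost without control replicate 1 (0.101) or 2 (0.17) or replicate 1 at 100 mg/kg (0.0898). In all 2723 genes changed, 1469 higher and 1254 lower, against 1189 higher of 2620 with median scaling. At this dose 12 lists were called (0 with an estimated correlation, smallest adjusted p = 0.0619). The lung lineage list, called at the lower doses, was not (median 0.35, adjusted p = 0.0731), nor was its difference from 75 mg/kg (adjusted p = 0.107). The count was 1368 without control replicate 1 and 1556 without 2, and with unnormalized signals 842 of 2686 genes were higher.

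In all 362 genes were higher and 321 lower at every dose. Of the genes changed at both 75 and 100 mg/kg, 767 were higher and 720 lower in both, against 108 and 89.4 for independent lists, which leave out the shared controls. For 75 and 87.5 mg/kg these were 371 and 338 (29.5 and 25.7 if independent), for 87.5 and 100 mg/kg 386 and 333 (47.8 and 36.7), and 0 genes went opposite ways in any pair. Unchanged groups simulated 100 times with shared controls, a test added after the data were seen, gave at most 0.02 shared calls on average. Their top genes in lists as long as the real ones shared 480 and 429, 207 and 188, and 243 and 208 in the same order of pairs. Part of the overlap can therefore come from the shared controls. Comparing each dose of a pair with a different control tumour was not done. Across genes, which are not independent replicates, log2 changes correlated at 0.894, 0.891 and 0.88 for 75 with 87.5, 75 with 100 and 87.5 with 100 mg/kg. The same controls enter every dose, and unchanged groups simulated with them correlated at 0.632, 0.633 and 0.599. The covariance exceeded the simulated one by 0.243, 0.354 and 0.285.

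Between 75 and 87.5 mg/kg (n = 4 and 3), 0 genes differed by limma, with 1036 at an unadjusted p under 0.05. The smallest p belonged to IL18R1, an interleukin receptor gene at least 2.11-fold higher at 87.5 mg/kg, and to TENT5A (log2 -0.65, SE 0.10), both with an adjusted p of 0.239. Camera at the preset correlation called 12 lists, 8 higher and 4 lower at 87.5 mg/kg, among them mesenchymal (median 0.34, adjusted p = 0.297 with an estimated correlation) and hypoxia genes (median 0.21, adjusted p = 0.639 with it). With an estimated correlation 0 were called, and fry called 0. Leaving out replicate 3 at 87.5 mg/kg gave 2 genes, with IL18R1 passing (adjusted p = 0.00303), and leaving out replicate 2 at 75 mg/kg gave 3.

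Between 75 and 100 mg/kg (n = 4 and 3), the hormone precursor gene POMC was at least 2.05-fold higher at 100 mg/kg (adjusted p = 0.0417), RIPPLY2 at least 1.6-fold and TMSB15B by log2 1.64 (SE 0.32, detected in 1 of 4 at 75 mg/kg). HNRNPL, a splicing factor gene (log2 -1.68, SE 0.28, adjusted p = 0.0333), ANKRD36B (log2 -1.71) and the transcription factor gene PROX1 (log2 -1.48) were lower. In all 82 genes differed, 30 higher and 52 lower, against 53 higher of 82 with median scaling. The epithelial list alone was called, lower at 100 mg/kg (median -0.14, adjusted p = 0.0195, adjusted p = 0.535 with an estimated correlation), and fry called 0. Without replicate 1, 2, 3 or 4 at 75 mg/kg the count was 1, 2, 0 and 3, without replicate 1, 2 or 3 at 100 mg/kg 2, 0 and 1, and without replicate 1, 2 or 3 at 87.5 mg/kg 53, 330 and 144. All 6 named genes lost their calls without any 1 tumour at 75 mg/kg or without replicates 2 and 3 at 100 mg/kg, with adjusted p-values up to 0.164 over the settings that ended them.

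Between 87.5 and 100 mg/kg (n = 3 each), the smooth muscle myosin gene MYH11 was at least 2.71-fold and the coagulation factor gene F7 at least 1.63-fold higher at 100 mg/kg, and INPP5J higher by log2 1.45 (SE 0.22, adjusted p = 0.0353). F7 had log2 0.11 (adjusted p = 0.923) with no detection filter and did not pass with the replicate block (0.106). The plasminogen activator gene PLAT (log2 -2.54, SE 0.35, adjusted p = 0.0353), the laminin gene LAMB3 (log2 -2.01) and PRRX2 (log2 -1.81, detected in 1 of 3 at 100 mg/kg) were lower. In all 96 genes differed, 43 higher and 53 lower, against 57 higher of 97 with median scaling. Camera called 13 lists, 12 of them lower at 100 mg/kg, with YAP and TAZ targets (median -0.50, adjusted p = 0.172 with an estimated correlation) first, 0 passed with an estimated correlation, and fry called 1. The count was 277 without replicate 2 at 87.5 mg/kg, 12 without replicate 3 and 0 without replicate 1. It was 0 without either control, without replicate 1 at 75 mg/kg and without replicates 1 or 2 at 100 mg/kg, 1 without replicate 3 at 100 mg/kg, and 49 and 6 without replicates 2 and 4 at 75 mg/kg, and the 6 named genes lost their calls in each setting that gave 0 or 1.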

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

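The test for the normalization of the epithelial and adhesion lists and that of probe names were chosen only after the results were seen.

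Lower epithelial, mesenchymal and adhesion lists in treated tumours are the first pattern, and brightness does not account for it, since each of the 3 medians lay at percentile 0.01 of 10000 matched lists, the smallest they can give. The test written before the data, on the medians of all 3 lists, met its prediction for normalization, because the mesenchymal list kept 49.4%. Relative to all genes, a later measure, epithelial and adhesion lists kept at least 57% of their medians without quantile normalization or background correction. Normalization is therefore not the whole cause for these 2 lists. The mesenchymal list kept 93% on that measure with median scaling in place of quantile normalization, 50.1% without background correction (49.4% of the median itself) and 44.3% with unnormalized signals, which drop both steps. Its size therefore depended on background correction. The list was dimmer, with a mean control log2 signal of 8.73 against 10.8 in each of the other 2 lists. These settings cannot tell whether the correction inflated or restored its change. Less mouse fibroblast RNA cannot be told apart from a change in the tumour cells under ceritinib, untested, since the 20 mesenchymal genes outside the fibroblast list had a median of -0.942 but an upper quartile of 0.20. COL1A1, abundant in fibroblasts, had 9.71 in controls and 8.94, 9.31 and 8.66 at rising dose.

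The second pattern is the difference between 87.5 and 100 mg/kg, 96 genes in limma. Without replicate 2 at 87.5 mg/kg, which stood apart on the second component, 277 genes differed, so the count may hang on 1 tumour, and it was 0 without either control. Of the 10 splits of the 6 tumours, the real one gave 96 and the highest other 0, but 10 splits are too few for a share under 0.05. A dose effect stays open, untested beyond these comparisons.

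For the other counts, chance is unlikely for treated against control tumours. Of 66 choices of 2 tumours as controls, only the real one gave 1839 genes, with the 10 treated as 1 group, and the highest other gave 5. A share of 1 in 66 is the smallest these splits can give. Slides and labelling batches were not given, so the splits cannot tell treatment from a shared handling difference of the 2 control arrays. For 75 against 100 mg/kg, 1 of 35 splits gave 82 genes and the others at most 0, which speaks against chance, but without any 1 of those 7 tumours the count was 0 to 3, with the replicate block 2 and with unnormalized signals 5. The splits put the real grouping above the others, and the genes behind it are not settled. For 75 against 87.5 mg/kg the real count of 0 is reached by 35 of 35 splits by construction, so the splits decide nothing there, and the highest gave 8.

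The third pattern concerns probe names. Through the text table's identifiers, probes of 1 gene correlated at 0.0577, and 222 genes changed under both namings, against 200 by chance among 6699 tested under both. A row order that differs from the signals is consistent with both values. No biological explanation was tested.

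Among the 4 tumours at 75 mg/kg, 7 of 158 examined genes had 1 tumour far from the others, where chance at 1 in 20 gives 7.9. The distance to the nearest tumour, as a share of the range, was 0.948 for BHLHE40 (replicate 2 at 13.85, others 13.19 to 13.23) and 0.831 for VWF (replicate 2 at 8.59, others 9.12 to 9.23). For replicate 3 it was 0.853 in RET (9.93, others 8.87 to 9.02), 0.906 in TNFAIP2 (9.87, others 10.3 to 10.35) and 0.874 in NFKB1 (11.9, others 12.05 to 12.07). FHOD3 (0.94, replicate 2 at 5.35, others 5.01 to 5.03) and FAP (0.84, replicate 1 at 5.18, others 5.81 to 5.93) were detected in 0 of 4 of these tumours.

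Differences between doses were tested directly in the fit. From 75 to 100 mg/kg the log2 differences were 1.849 for POMC, 1.638 for TMSB15B, 1.585 for RIPPLY2, -1.706 for ANKRD36B, -1.681 for HNRNPL and -1.479 for PROX1. From 87.5 to 100 mg/kg they were 2.534 for MYH11, 2.026 for F7, 1.447 for INPP5J, -2.537 for PLAT, -2.014 for LAMB3 and -1.806 for PRRX2. For genes undetected at the lower dose these are fitted values, not bounds.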

How the results depend on the processing

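The names of the text table were an alternative chosen after the data were seen. No result passed a test in the opposite direction, but among genes detected on at least 6 arrays the fibroblast median turned from -0.75 to 0.0988. Leaving out each tumour gave 719 to 2844 changed genes for treated tumours, 556 to 2260 at 75 mg/kg, 179 to 972 at 87.5 mg/kg and 1368 to 3250 at 100 mg/kg. It gave 0 to 3 genes between 75 and 87.5 mg/kg, 0 to 330 between 75 and 100 mg/kg and 0 to 277 between 87.5 and 100 mg/kg. With 1 control left, that tumour is assumed to vary like the other groups. The mean correlation of dose effects, 0.888, ranged from 0.842 (without replicate 3 at 87.5 mg/kg) to 0.894 and was 0.873 without a detection filter.

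Requiring also a change of more than log2 1 gave 823, 808, 418 and 1229 genes for treated tumours and the 3 doses, and 36 and 41 for 100 against 75 and against 87.5 mg/kg. Unnormalized signals gave 2966 at 75 mg/kg, 1784 at 87.5 mg/kg and 5 between 75 and 100 mg/kg. Array weights gave 1344 at 87.5 mg/kg and 507 and 428 for 100 against 75 and 87.5 mg/kg. A fit of only the compared groups gave 157 at 87.5 mg/kg, 416 between 75 and 100 mg/kg and 1 between 87.5 and 100 mg/kg, from fewer tumours. No detection filter gave 30 between 87.5 and 100 mg/kg. The text table's names gave 432 at 87.5 mg/kg and 167 between 75 and 100 mg/kg. Camera with an estimated correlation called 0 of the 13 lists. The cause was not tested for these.

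Replicate numbers did not pair the tumours, since deviations from the group mean correlated at a median of -0.0305 in 15 pairs with the same number and -0.00651 in 38 with different numbers. A block for replicate number gave 975 genes at 75 mg/kg, 500 at 87.5 mg/kg and 2 and 9 for 100 against 75 and 87.5 mg/kg. Of the values of single genes under alternatives, 3551 kept their side of the threshold, 272 lost a call and 67 gained 1, and of those of lists 652, 24 and 5. Signal over background limits genes detected on few arrays.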

Other observations

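The test of gene families, and its repeat without each tumour, were chosen only after the data were seen. Families with at least 8 measured members sharing a name stem were compared with all other tested genes for their counts of risen and fallen members by one-sided Fisher's exact tests, 414 tests in 207 families, adjusted together. Such tests treat genes as independent draws, although all were measured on the same 12 tumours. Their p-values therefore do not measure the spread between tumours. Of 9 cadherin genes, whose proteins join cells to each other, 7 fell and 0 rose (adjusted p = 0.000581). Besides CDH6, CDH2, CDH11 and CDH1, these were CDH26 (log2 -2.03), the placental cadherin gene CDH3 (log2 -1.67) and CDH15 (log2 -1.42), and 7 fell with each of 5 background and normalization settings. Without control replicate 1 or 2 the count was 4, and the family passed only without replicate 1 (adjusted p = 0.0164 and 0.102). Of 8 ADAM genes, which encode membrane proteases and their relatives, 5 fell and 0 rose (adjusted p = 0.0353), among them ADAM8 (log2 -2.03), ADAM19 (log2 -1.65) and ADAM9 (log2 -1.39), and 5 fell in all 5 settings, but 3 without either control (adjusted p = 0.101 and 0.255). Of 12 annexin names 7 fell and 0 rose (adjusted p = 0.00501), a count that includes pseudogenes of ANXA2 whose probes can share its signal, and 7 or 8 fell in the 5 settings, but 3 and 4 without control replicates 1 and 2 (adjusted p = 0.221 and 0.182). Names that begin with CD, which are no true family, were the only stem that passed upward, 11 of 35 risen and 5 fallen (adjusted p = 0.0386). The stem did not pass without either control. It also failed without replicate 1, 2 or 3 at 75 mg/kg (adjusted p = 0.133, 0.0725 and 0.08). The same held without replicate 1 at 87.5 mg/kg (0.138) or replicate 3 at 100 mg/kg (0.0711), while it passed without each other treated tumour.

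Collagen genes moved both ways, 8 of 24 fallen and 6 risen, and the count of fallen genes did not pass (adjusted p = 0.0672). Of 4598 detected probes without a gene symbol, 505 changed in treated tumours (11%), 238 higher and 267 lower, against 18.8% of named genes.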
